A study of Mus musculus with 14 samples.

How the data were processed

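RNA was measured in skeletal muscle and brain of WT mice and of mice with a gene trap in Cugbp1 (now named Celf1), all taken at 1 day of age, on 14 Agilent arrays with 1 colour (Cy3). The deposited table held 55681 probes with values in the unit intensity on a linear scale, and 129 of its cells were blank. Per the labels, the values came from Agilent Feature Extraction; its version and any further steps were not given in the sources used here. The 75th percentiles of the named probes ranged from 883 to 1398 between arrays, so no scaling between arrays was visible in the deposited values. The lowest value of each array lay between 2.04 and 3.51, and 22.2% to 30.4% of the probes of an array lay within 2-fold of its lowest value. Detection flags were not used here, and the number of arrays limits the precision of every value.

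Probes were named with the probe annotation of the series. Of the probes in the table, 30626 carried 1 gene symbol, 0 carried several and 25055 were not listed there. Of the named probes, 30332 matched a gene of the mouse assembly GRCm38.p6 by gene identifier, which was used only for names and for the order of genes along chromosomes; the series names no genome build, and no positions are given. Each gene was represented by the probe with the highest mean over all 14 arrays, which gave 21893 genes, 6807 of them with at least 2 probes. A blank value was present in 48 genes, and those arrays were not used for these genes.

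The plan written before the data were examined called for log2 of the deposited values without scaling as the main setting. Because the values proved to be unscaled intensities, the 75th percentile of the log2 intensities of the named probes was instead subtracted from each array. That scaling had been planned as an alternative, and the values without scaling became an alternative added after seeing the data. Levels are therefore log2 intensities relative to the 75th percentile of the array, and intensities quoted beside them are means of the deposited values.

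Samples were grouped by tissue and genotype as labelled, with 3 WT and 3 KO arrays of muscle and 4 WT and 4 KO arrays of brain. KO was compared with WT within each tissue by limma 3.58.1 in R 4.3.3, with linear models and moderated statistics, no trend and no robust option, 2-sided, for all named genes. The difference between tissues in the KO effect was tested in 1 limma model with 4 group means over all 14 arrays. Benjamini-Hochberg adjusted p under 0.05 was the threshold. P values measure the spread between samples; the labels give no litter, sex or date, and do not state whether the brain and muscle samples of a number came from the same mouse. Whether array numbers pair WT with KO samples was not settled. Correlations of same-numbered deviations were 0.20, -0.26 and 0.12 in muscle, and 0.18, 0.04, 0.23 and 0.01 in brain, without values of differently numbered arrays to set beside them. The main models had no block, as planned, and the array number as a block was an alternative.

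The 42 gene lists were fixed before the data were examined, of which 29 were tested in muscle and 31 in brain. They covered RNA-binding proteins, reported CUGBP1 targets, neighbours of Celf1, fibre types, metabolism, stress, growth, interferon response, and markers of cell types that each tissue sample could hold. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a tissue, and again with an estimated correlation and with fry. Members were also counted as past the threshold over all genes and adjusted over the list alone. A list score per array is the mean over members of the log2 level minus the mean of the gene over the arrays of the tissue, and scores were compared by exact permutation tests, 2-sided. The KO effects on the lists in the 2 tissues were compared by 1400 assignments of the genotype labels within tissues.

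Named genes were chosen by a rule written before the data were examined. It took Celf1 in both tissues, and per tissue the 10 largest rises and 10 largest falls past the threshold whose KO arrays all lay on 1 side of the WT arrays. Olfactory, vomeronasal and taste receptor genes and predicted genes were left out there, and where no gene passed, the 10 genes with the smallest p were given as values only. The rule also took up to 4 members of each list by p, the 5 rises and 5 falls with the smallest p past the threshold in the difference between tissues, up to 10 genes past it in both tissues, and the sex chromosome genes. List members are named only for lists that passed camera and for the 3 lists on CUGBP1 and its neighbours. Genes named outside this rule are marked as chosen after their values were seen.

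Fold changes of the 2 tissues were correlated across genes and compared with 100 splits of the arrays within tissues, the real split included. Counts of genes and lists were also taken over all 10 splits of the muscle arrays and 35 splits of the brain arrays. For position, 21784 genes were placed in 228 windows of up to 100 genes in chromosome order, and the genes at unadjusted p under 0.01 were counted per window and compared with 1000 shuffled gene orders; this test was chosen after seeing the data. Alternatives planned beforehand were quantile and median scaling, only genes above the median level, the mean of a gene's probes, every probe on its own, trend and robust options, array weights and a plain test without moderation. Also planned were a threshold with an absolute log2 fold change of at least 1, adjusted p under 0.10, all 14 arrays in 1 model, sex chromosome genes left out, the array number as a block, same-numbered arrays as a random block, and each array left out in turn. Alternatives added after seeing the data were no scaling, 50 added to each intensity, the filter on level together with trend and robust options, the Xist level as covariate, and leaving out the WT arrays high in hypoxia genes. Median log2 fold changes of all genes were -0.03 in muscle and 0.01 in brain with the scaling used, and 0.14 in muscle and 0.03 in brain without scaling; changes are given relative to the 75th percentile.

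The code was tested on simulated data with the array numbers and spreads of each tissue. In muscle, limma recovered 0 of 100 genes simulated at an absolute log2 fold change of 1 and 25 of 100 at 2, with 0 false calls. In brain it recovered 51 of 100 at 1 and 89 of 100 at 2, with 7 false calls. A list shifted by -1 on the log2 scale passed camera in both tissues, at adjusted p of 3.78e-08 in muscle and 8.73e-50 in brain. With an estimated correlation its adjusted p was 0.0736 in muscle and 8.97e-05 in brain. At the preset correlation 0 other lists were called. Genes were simulated independently of each other, whereas estimated correlations in the real lists reached 0.80 (interferon, muscle) and 0.76 (hypoxia, brain). The simulation therefore does not show how often camera calls lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.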

Results

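Gene expression was measured in skeletal muscle and brain of mice at 1 day of age to ask how loss of Cugbp1 alters the transcriptome of both tissues. Cugbp1, now named Celf1, encodes CUGBP1, an RNA-binding protein that acts in splicing, decay and translation of mRNAs. Per the labels, the knockout (KO) mice derive from embryonic stem (ES) cells with a gene trap vector ahead of the start codon, and wild-type (WT) mice served as controls. There were 3 WT and 3 KO arrays of muscle, and 4 WT and 4 KO arrays of brain, each with RNA of 1 sample. Levels of all genes correlated between arrays at r of 0.968 to 0.987 within muscle and 0.986 to 0.994 within brain. Xist, the RNA that coats the inactive X chromosome of females, was low on 1 of 3 WT and 1 of 3 KO arrays of muscle, and on 2 of 4 WT and 1 of 4 KO arrays of brain. The list of sex chromosome genes did not pass camera in muscle (median log2 fold change -0.065, adjusted p = 0.912) or in brain (median -0.60, adjusted p = 0.913). It holds Xist and genes of the Y chromosome, which went in opposite directions across arrays, so this directional test cannot show an imbalance of sex.

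Celf1 itself was lower in every KO array than in every WT array of its tissue. In brain, Celf1 fell by 1.71 on the log2 scale (SE 0.082, n = 4 per genotype, adjusted p = 0.000534), a 3.27-fold lower level. The deposited intensities of its probe A_51_P204845 were 1637 to 2086 in KO and 4854 to 6961 in WT brain. In muscle the log2 fold change of Celf1 was -2.77 ± 0.30 (SE, n = 3 per genotype), a 6.83-fold lower level, with intensities of 498 to 758 in KO and 3099 to 4696 in WT. With 3 arrays per genotype this difference did not pass over all genes in limma (adjusted p = 0.312), and it passed when all 14 arrays shared 1 model (adjusted p = 5.35e-05; range over the alternatives 5.35e-05 to 1.00). That model takes its spread from the brain arrays as well, where Celf1 varied less than in muscle. The other probes of Celf1 gave KO levels of 6.43% and 13.6% of WT in muscle, and of 25.6% and 34.5% of WT in brain. The brain call was lost with the array number as a block (adjusted p = 0.230) and without brain WT arrays 3 and 4 together, an alternative chosen after seeing the data (adjusted p = 0.0800; range over the alternatives 3.42e-06 to 0.230). The KO effect on Celf1 in brain minus that in muscle was 1.06 ± 0.26 on the log2 scale, which did not pass over all genes (adjusted p = 1.00).

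**Figure D1:**
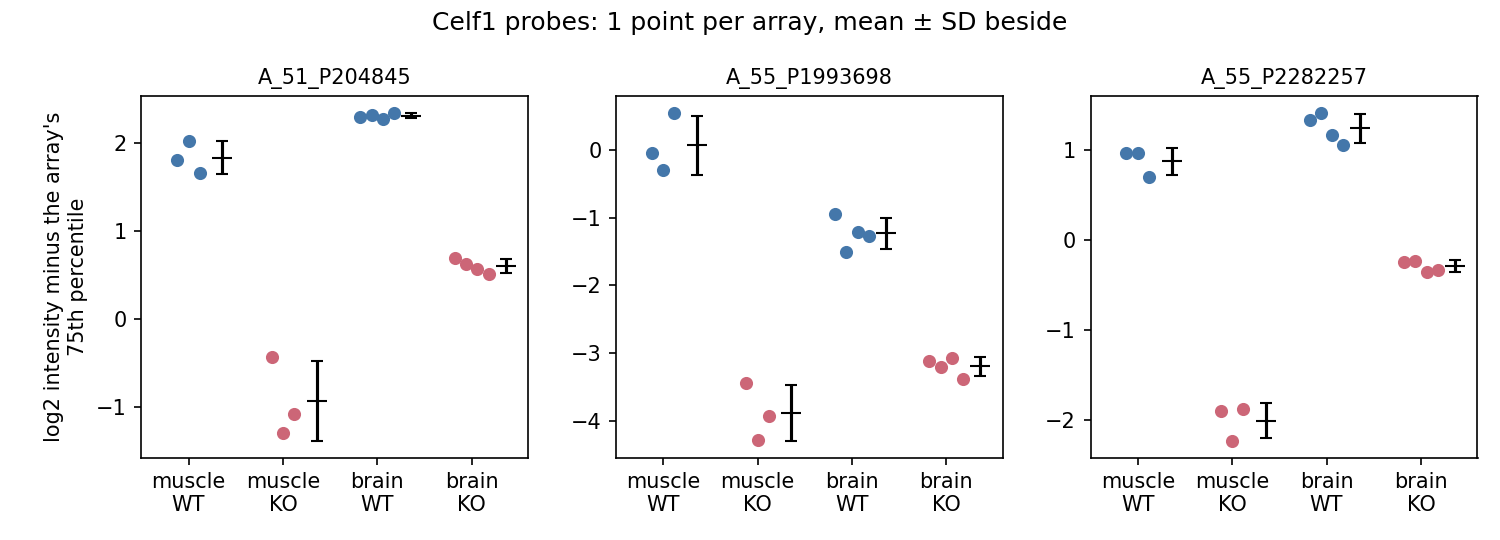
Level of Celf1 on each array (log2 intensity relative to the 75th percentile of the array) for its 3 probes, by tissue and genotype; each point is 1 array, with the mean and SD beside. The KO arrays lie below the WT arrays of the same tissue for each probe, with 3 arrays per genotype in muscle and 4 in brain.

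In brain, 5 genes passed the threshold, 3 higher and 2 lower in KO. Beside Celf1, Serinc4, a member of the serine incorporator family of membrane proteins, rose by 1.02 ± 0.10 on the log2 scale (SE, n = 4 per genotype, adjusted p = 0.0265), from a mean intensity of 121 to 245. Zbtb7c, a zinc finger protein of the BTB family, rose by 1.30 ± 0.13 (adjusted p = 0.0399), from 12.5 to 31.5. Over the alternatives its log2 fold change ranged from 0.36 to 1.37. Htr5a, which encodes a serotonin receptor, fell by 1.59 ± 0.14 on the log2 scale (adjusted p = 0.0243), from 10.4 to 3.50, an intensity close to the lowest values of the arrays. The olfactory receptor gene Olfr874, chosen after its values were seen, rose by 1.59 ± 0.14 (adjusted p = 0.0243) between similarly low intensities of 2.91 and 8.94. The sizes of the fold changes of Htr5a and Olfr874 are therefore not exact. For all 5 genes, the 4 KO arrays lay on 1 side of the 4 WT arrays. At unadjusted p under 0.001 there were 57 genes, 11 higher and 46 lower in KO, and at unadjusted p under 0.05 there were 1828, against 1095 expected by chance. KO and WT arrays did not overlap in 308 genes that were higher and 535 that were lower, 3.85% of genes, where chance gives 2.86%.

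The brain count was 0 with the array number as a block (1656 at unadjusted p under 0.05), 0 without WT arrays 3 and 4 together (784 at unadjusted p under 0.05), 2 in a plain test without moderation and 2158 with array weights. It also depended on single arrays. The count was 1 without WT array 3, WT array 4 or KO array 2, where the gene left was Celf1, 2 without KO array 4, 3 without KO array 1 or KO array 3, 4 without WT array 1 and 9 without WT array 2. Among these models the calls of Htr5a (adjusted p = 0.0117) and Serinc4 (adjusted p = 0.0432) held only without WT array 2, and Zbtb7c passed in none (adjusted p = 0.0563 to 0.212). Over all alternatives the adjusted p of Htr5a ranged from 0.00564 to 0.998, that of Serinc4 from 0.00657 to 0.542 and that of Zbtb7c from 0.00657 to 0.545.

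Interferon response genes, which cells switch on after interferon signalling, fell together in KO brain. All 24 measured members had a negative log2 fold change, with a median of -0.86, a 1.81-fold lower level, and in 17 of them all 4 KO arrays lay below all 4 WT arrays. The list passed camera (adjusted p = 4.16e-25), also with an estimated correlation (adjusted p = 0.00671), and passed fry (adjusted p = 5.62e-05). Adjusted over the list alone, 19 members were lower and 0 higher, while over all genes 0 passed in limma. Oas1a, an antiviral oligoadenylate synthetase, had a log2 fold change of -1.24 ± 0.14 (adjusted p = 0.0570 over all genes, 0.000304 adjusted over the list alone). The antiviral GTPase gene Mx2 stood at -1.11 ± 0.14, and Isg15, a ubiquitin-like modifier, at -0.86 ± 0.10, both also at 0.000304 adjusted over the list alone. Rtp4, another interferon-induced gene, stood at -0.90 ± 0.14. The list score was -0.42 ± 0.038 (SD) in the 4 KO and 0.42 ± 0.052 in the 4 WT arrays (exact permutation p = 0.0286, the smallest these arrays allow, and 0.443 adjusted over the brain lists). The median was -0.46 with 50 added to each intensity. Without brain WT arrays 3 and 4 it was -0.89, with adjusted p = 0.0648 at an estimated correlation (range over the alternatives 3.46e-29 to 0.0648).

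Of 31 brain lists, 8 passed camera, 1 higher and 7 lower in KO, and 14 passed without WT array 1. Beside the interferon list, 7 passed with the preset correlation only. With an estimated correlation the adjusted p was 0.643 for each of the 7, and with fry it was 0.459 to 0.529. Adjusted over the list alone, as over all genes, 0 members of these 7 lists passed. Markers of astrocytes fell, with 19 of 19 members below 0 and a median log2 fold change of -0.31 (adjusted p = 1.08e-07; range over the alternatives 1.25e-10 to 0.978). Among them, the glutamate transporter gene Slc1a2 stood at -0.79 ± 0.24 and Gfap, an intermediate filament of astrocytes, at -0.84 ± 0.30. Neutrophil genes fell by a median of 0.81 on the log2 scale (16 of 17 below 0; adjusted p = 1.19e-05; range 1.03e-07 to 0.747), with S100a8, a calcium-binding protein of neutrophils, at -1.57 ± 0.60. The neutrophil scores were -0.59 to -0.10 in the KO and 0.028 to 1.09 in the WT arrays, so they too separated the genotypes (exact permutation p = 0.0286). Macrophage and microglia genes fell by a median of 0.26 (18 of 22 below 0; adjusted p = 1.73e-05; range 4.31e-10 to 0.978), with the microglial receptor gene Trem2 at -0.51 ± 0.16. The score of this list on WT array 1, -0.21, lay below the KO mean of -0.14 ± 0.061 (SD), and its exact permutation p was 0.114. Genes of skeletal muscle, present at low levels in the brain samples, fell by a median of 0.22 (15 of 19 below 0; adjusted p = 0.0351), with the fast troponin gene Tnni2 at -1.03 ± 0.32. Cell cycle genes rose by a median of 0.17 (31 of 37 above 0; adjusted p = 0.000922), with Top2a, the topoisomerase of dividing cells, at 0.45 ± 0.21.

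Hypoxia genes and glycolysis genes also fell in KO brain by camera, and both patterns lay in 2 of the WT arrays. The hypoxia list had a median of -0.72 (18 of 19 below 0; adjusted p = 1.70e-06), with the carbonic anhydrase gene Car9 at -1.10 ± 0.36 and the prolyl hydroxylase gene Egln3 at -1.10 ± 0.43. Glycolysis genes had a median of -0.45 (18 of 19 below 0; adjusted p = 2.69e-05), with the lactate dehydrogenase gene Ldha at -0.71 ± 0.33 and the triose phosphate isomerase gene Tpi1 at -0.74 ± 0.34. Adjusted p was 0.643 for both with an estimated correlation. The hypoxia score was 1.03 on WT array 3 and 1.19 on WT array 4, against -0.16 and -0.51 on WT arrays 1 and 2 and -0.62 to -0.14 on the KO arrays. WT arrays 3 and 4 also had the highest scores for astrocyte genes (0.50 and 0.44, against -0.14 and -0.0020 on WT arrays 1 and 2) and the lowest for cell cycle genes (-0.23 and -0.24). Without these 2 arrays, an alternative chosen after seeing the data, the medians were -0.027 for hypoxia, -0.047 for glycolysis and 0.014 for cell cycle genes, and none of the 3 passed (adjusted p = 0.930; ranges over the alternatives 2.92e-09 to 0.978, 1.17e-06 to 0.978 and 4.75e-06 to 0.978). Astrocyte, macrophage and neutrophil genes then had medians of -0.10, -0.15 and -0.33, and skeletal muscle genes one of -0.47. These lists still passed camera at the preset correlation (adjusted p = 0.0351, 0.0472, 0.00367 and 1.75e-06), where 6 brain lists passed in all. With an estimated correlation their adjusted p was 0.747 to 0.978. The cell cycle median was 0.29 without WT array 1 and 0.11 without WT array 3, and the call was lost without KO array 1 (adjusted p = 0.115). The call of the skeletal muscle list was lost without WT array 2 (adjusted p = 0.574) or KO array 2 (adjusted p = 0.139; range over the alternatives 1.75e-06 to 0.747), and its median was -0.090 without KO array 2 and -0.35 without WT array 3.

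The other 23 brain lists did not pass camera. Among them were the RNA-binding proteins related to CUGBP1 and MBNL (median log2 fold change 0.029, adjusted p = 0.465), where the splicing regulator gene Ptbp2 stood at 0.31 ± 0.11. The reported CUGBP1 target mRNAs (median -0.055, adjusted p = 0.449) and the chromosome 2 neighbours of Celf1 (median -0.021, adjusted p = 0.478) did not pass either. Lists of neurons, excitatory and inhibitory neurons, neural progenitors, oligodendrocytes, choroid plexus, meninges, pituitary, hindbrain, forebrain, and olfactory and retinal cells had medians of -0.15 to 0.15. The lists of oxidative phosphorylation, fatty acid oxidation, imprinted, unfolded protein, immediate early, glucocorticoid, endothelial and blood cell genes had medians of -0.27 to 0.041. Of the blood cell list, 3 members were higher adjusted over the list alone and 0 over all genes in limma. The mean of the pituitary and hypothalamus list and that of the olfactory and retinal list were above 0 while their medians were below 0, and the camera direction was up for the first and down for the other.

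**Figure D2:**
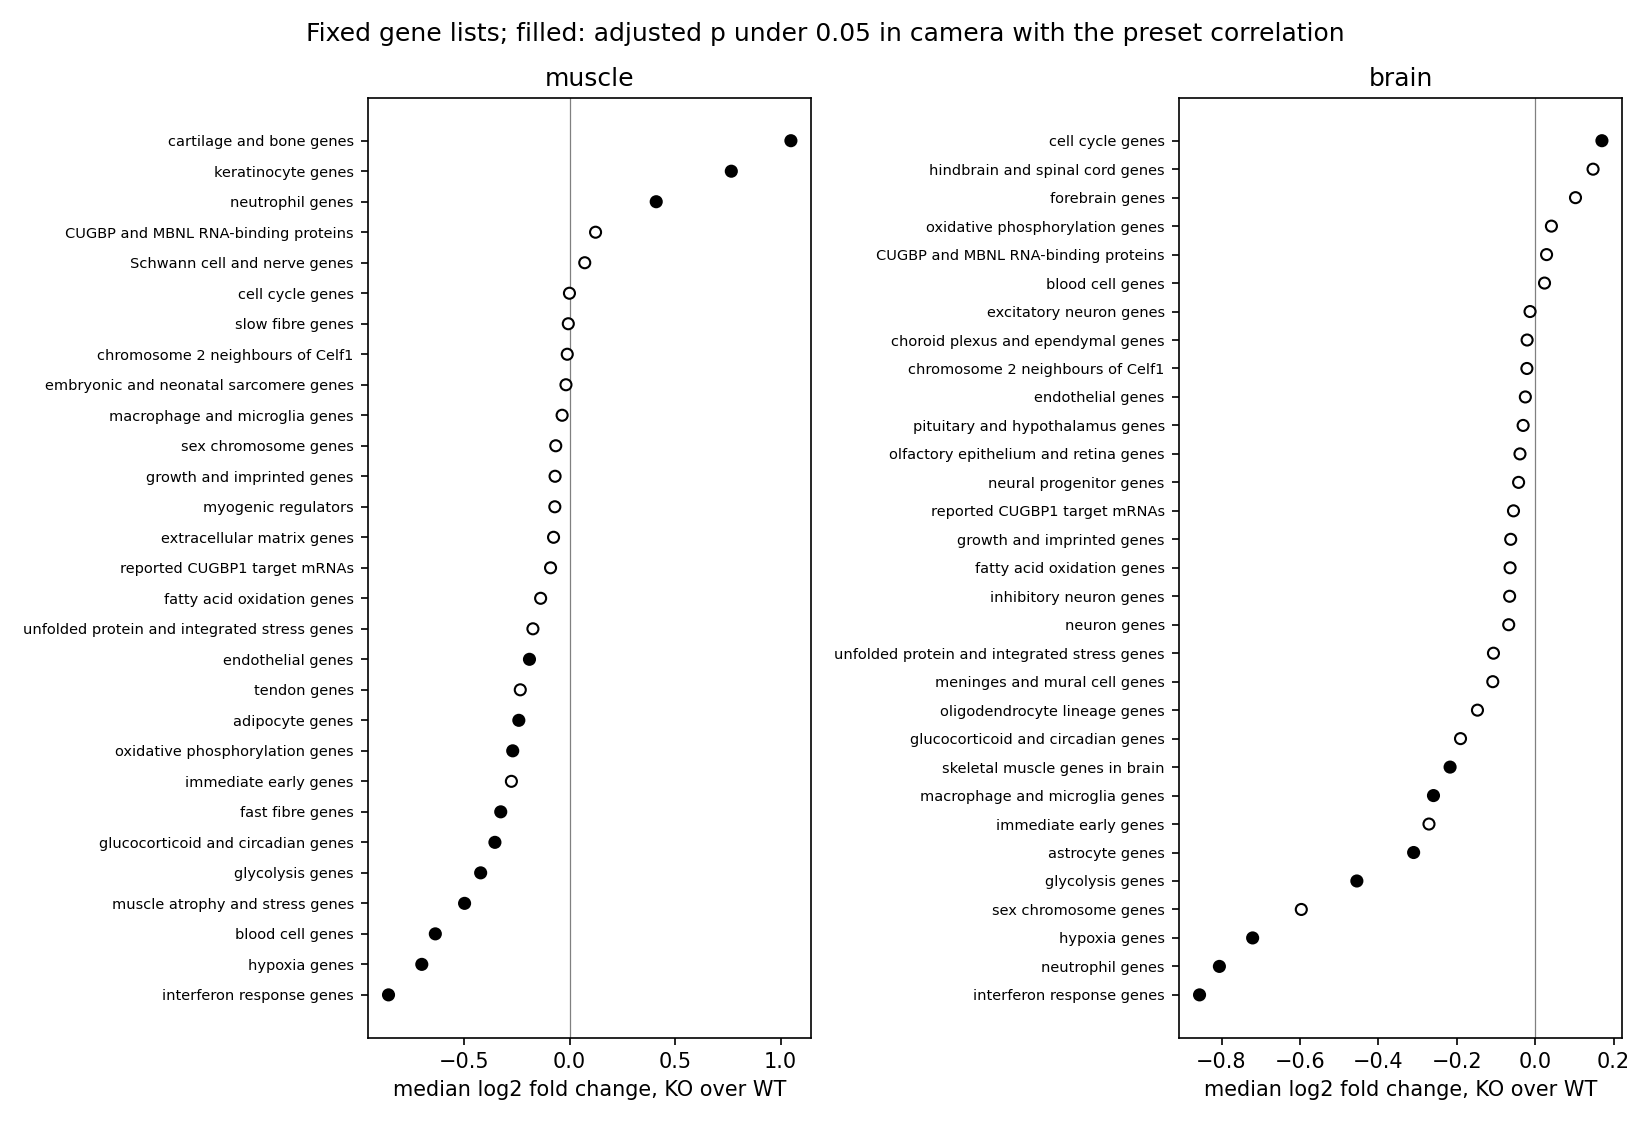
Median log2 fold change (KO over WT) of each gene list in muscle and in brain, 1 point per list, with filled points for lists that passed camera at the preset correlation. Interferon response genes lie at -0.86 in both tissues, and cartilage and bone genes at 1.05 in muscle.

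In muscle, 0 genes passed the threshold in limma, with 341 genes at unadjusted p under 0.05 against 1095 expected by chance; a plain test without moderation also gave 0, with 320 at unadjusted p under 0.05. The smallest adjusted p was 0.215, so the following are given as values. Rab6b, a small GTPase of Golgi traffic, stood at 2.60 ± 0.22 (SE, n = 3 per genotype), with mean intensities of 961 in KO and 143 in WT. Ppp1r14d, an inhibitor subunit of protein phosphatase 1, stood at 4.94 ± 0.52 (intensities 110 in KO and 2.83 in WT), and Gchfr, a regulator of the GTP cyclohydrolase enzyme, at 3.35 ± 0.50. The collagenase gene Mmp13 stood at 5.44 ± 1.14, with mean intensities of 280 in KO and 2.75 in WT. The remaining 5 genes of the 10 with the smallest p, beside Celf1, were Spink5 (1.34 ± 0.23), Sag (1.67 ± 0.30), Caps2 (1.09 ± 0.21), Trpa1 (1.48 ± 0.30) and Cplx1 (1.40 ± 0.29), which encodes a protein of synaptic vesicle release. The mean WT intensities were 3.04 for Spink5, 4.27 for Sag, 3.54 for Caps2, 2.90 for Trpa1 and 7.56 for Cplx1. The lowest intensities of the 14 arrays were 2.04 to 3.51, so the sizes of the fold changes of Ppp1r14d, Mmp13, Spink5, Sag, Caps2 and Trpa1 are not exact. In all 10 the KO arrays lay on 1 side of the WT arrays. KO and WT arrays did not overlap in 407 genes that were higher and 457 that were lower, 3.95% of genes, where chance gives 10%. The count was 1 without KO array 2, 1 with only genes above the median level, 1 with 50 added to each intensity, and 9 when all 14 arrays shared 1 model.

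Of the 29 muscle lists, 13 passed camera with the preset correlation, 3 higher and 10 lower in KO; with an estimated correlation and with fry, 0 passed. Cartilage and bone genes rose by a median of 1.05 (19 of 20 above 0; adjusted p = 1.11e-12; adjusted p = 0.810 with an estimated correlation). The bone sialoprotein gene Ibsp stood at 6.03 ± 1.74 and the alkaline phosphatase gene Alpl at 2.19 ± 0.61; adjusted over the list alone 1 member, Mmp13, was higher, and over all genes 0. The score of this list was 1.90 and 1.37 on KO arrays 1 and 3 but -0.86 on KO array 2, within the WT range of -1.16 to -0.60. Its median was 0.62 without WT array 1, 0.66 without KO array 1 and 1.69 without KO array 2 (range of adjusted p over the alternatives 1.12e-32 to 0.975). Keratinocyte genes rose by a median of 0.77 (16 of 19 above 0; adjusted p = 1.22e-05; adjusted p = 0.362 with an estimated correlation), with the skin keratin genes Krt5 at 2.32 ± 0.99 and Krt14 at 1.44 ± 0.63. Its scores were 0.85 and 1.16 on KO arrays 1 and 2 and -0.38 on KO array 3, and its median was 0.49 without WT array 1, 0.44 without WT array 3 and 0.52 without KO array 2 (range of adjusted p 4.97e-11 to 0.975). Neutrophil genes rose by a median of 0.41 (13 of 17 above 0; adjusted p = 0.00370; adjusted p = 0.902 with an estimated correlation), with Mmp9 at 3.30 ± 0.97. The median of the neutrophil list was -0.22 without WT array 2 (adjusted p = 0.885; range over the alternatives 2.36e-07 to 0.975) and 0.83 without WT array 3.

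Among the 10 muscle lists that fell, interferon response genes had a median of -0.86, with 24 of 24 members below 0 (adjusted p = 2.15e-08; adjusted p = 0.902 with an estimated correlation). Isg15 stood at -1.69 ± 0.73 and Rsad2, an antiviral enzyme, at -1.61 ± 0.76; adjusted over the list alone 0 members passed. Scores of the interferon list overlapped between genotypes, at 0.91, -0.18 and 0.60 in WT and -0.71, 0.77 and -1.39 in KO (exact permutation p = 0.30, where 0.10 is the smallest possible). Its median was -0.52 without WT array 1, -1.47 without KO array 2 and -0.39 without KO array 3 (range of adjusted p over the alternatives 2.75e-28 to 0.975). Fast fibre genes fell by a median of 0.33 (16 of 18 below 0; adjusted p = 0.000927; adjusted p = 0.902 with an estimated correlation), with the calcium buffer gene Pvalb at -1.71 ± 0.42 and the fast myosin gene Myh4 at -1.37 ± 0.89. Glycolysis genes fell by a median of 0.42 (19 of 19 below 0; adjusted p = 1.22e-06; adjusted p = 0.810 with an estimated correlation), with the hexokinase gene Hk2 at -1.10 ± 0.50. Oxidative phosphorylation genes fell by a median of 0.27 (39 of 40 below 0; adjusted p = 1.14e-05; adjusted p = 0.902 with an estimated correlation), with Cox7a1, a subunit of cytochrome oxidase, at -0.82 ± 0.49. The call of the fast fibre list was lost without WT array 2 (adjusted p = 0.194) or KO array 2 (adjusted p = 0.0795; range over the alternatives 9.83e-07 to 0.975). Its median was -0.17 without KO array 2. That of oxidative phosphorylation was lost without WT array 1 (median -0.12, adjusted p = 0.0814; range over the alternatives 2.67e-13 to 0.975), and its median was -0.43 without WT array 3 and -0.14 without KO array 2. The glycolysis median was -0.28 without WT array 3 (range of adjusted p 6.19e-08 to 0.975).

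A further 6 muscle lists fell by camera at the preset correlation, each at adjusted p = 0.902 with an estimated correlation and with 0 members past the threshold adjusted over the list alone. Hypoxia genes had a median of -0.70 (18 of 19 below 0; adjusted p = 3.75e-05), with the vascular growth factor gene Vegfa at -1.04 ± 0.65. The hypoxia score was 1.73 on WT array 3 and -0.79 to 0.044 on the other 5 arrays. Blood cell genes had a median of -0.64 (15 of 19 below 0; adjusted p = 0.00352), with the globin gene Hba-a1 at -0.92 ± 0.64. Atrophy and stress genes had a median of -0.50 (17 of 18 below 0; adjusted p = 0.00673), with the ubiquitin ligase gene Trim63 at -1.26 ± 1.09. Glucocorticoid and circadian genes had one of -0.35 (17 of 20 below 0; adjusted p = 0.00673), adipocyte genes one of -0.24 (14 of 18 below 0; 0.0379) and endothelial genes one of -0.19 (15 of 18 below 0; 0.0464). Without WT array 3 the medians were -0.020 for hypoxia (adjusted p = 0.590), -0.014 for blood cell (0.669), 0.063 for atrophy and stress (0.402) and 0.097 for glucocorticoid and circadian genes (0.707). Without WT array 1 the adipocyte median was 0.24 (adjusted p = 0.146) and the endothelial median -0.097 (0.512), while those of the atrophy and glucocorticoid lists were -0.89 and -0.54. Without WT array 2 the medians of the hypoxia, blood cell, atrophy, glucocorticoid and adipocyte lists were -1.18, -1.06, -0.88, -0.53 and -0.44. The adipocyte median was -0.57 without WT array 3, and without KO array 2 those of the atrophy, adipocyte and endothelial lists were -0.90, -0.46 and -0.31. Without KO array 1 the calls of the atrophy, glucocorticoid, adipocyte and endothelial lists were lost (adjusted p = 0.111 to 0.270), with a glucocorticoid median of -0.19. Without KO array 3 those of the hypoxia, atrophy, blood cell, adipocyte and endothelial lists were lost (adjusted p = 0.0603 to 0.964), with medians of -0.37, -0.086 and -0.029 for the last 3. Over the alternatives, adjusted p of these 6 lists ranged from 6.44e-08 to 0.975.

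The other 16 muscle lists did not pass camera, with adjusted p of 0.178 to 0.984. The RNA-binding proteins related to CUGBP1 and MBNL had a median of 0.12 (adjusted p = 0.243), the reported CUGBP1 targets one of -0.090 and the chromosome 2 neighbours of Celf1 one of -0.011 (both adjusted p = 0.886). The cardiac troponin T gene Tnnt2, a reported CUGBP1 splicing target, stood at 0.58 ± 0.37. As in brain, splicing and translation of the targets were not measured. Lists of embryonic sarcomere, slow fibre, myogenic regulator, matrix, tendon, Schwann cell, macrophage, cell cycle and imprinted genes had medians of -0.23 to 0.072. Fatty acid oxidation, unfolded protein and immediate early genes had medians of -0.14, -0.17 and -0.28. In the lists of chromosome 2 neighbours, embryonic sarcomere, slow fibre, myogenic regulator, matrix, macrophage, cell cycle and sex chromosome genes the median lay below 0 while the camera direction was up.

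**Figure D3:**
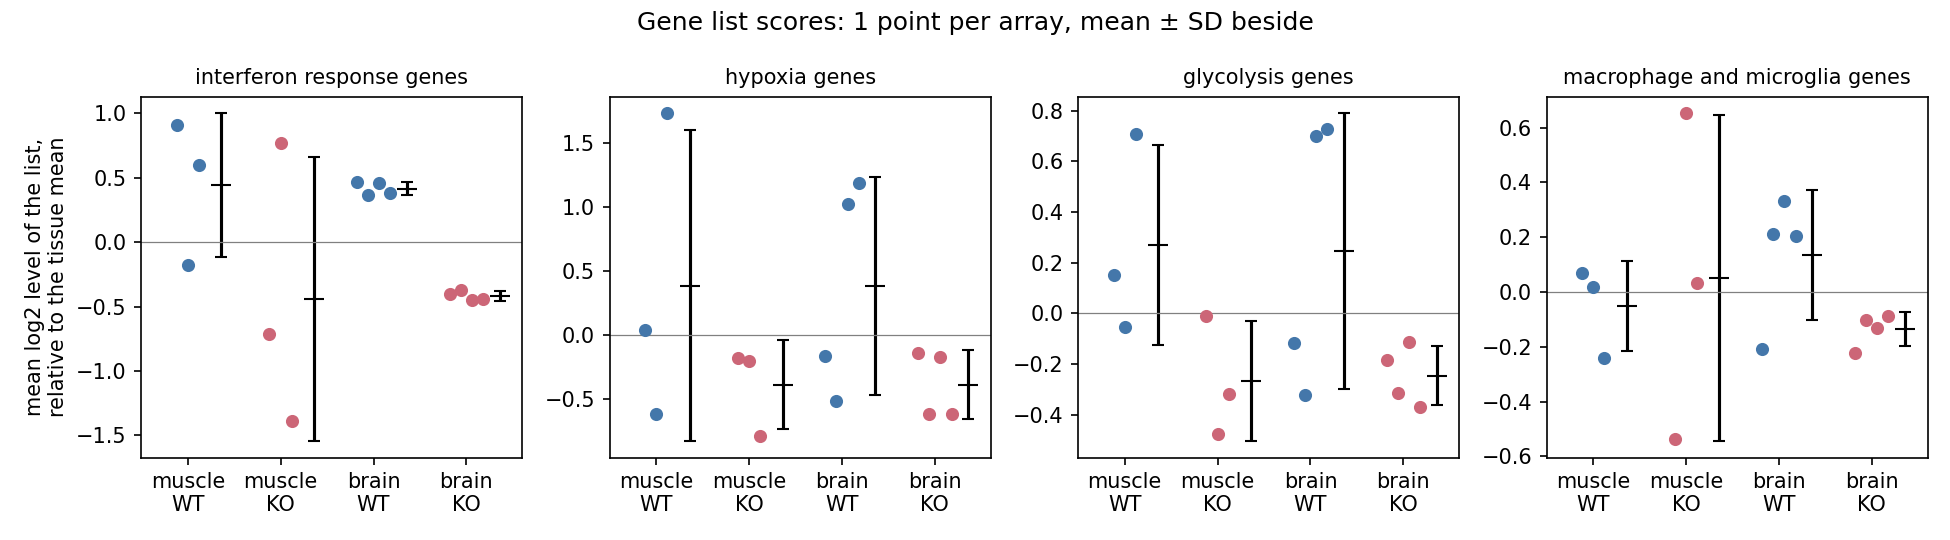
Scores of gene lists on each array (mean log2 level of the members relative to the mean of the tissue) for 4 lists, by tissue and genotype; each point is 1 array, with the mean and SD beside. The interferon scores of the 4 brain KO arrays lie between -0.45 and -0.37 and those of the 4 WT arrays between 0.37 and 0.46.

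The difference between tissues in the KO effect passed the threshold for 2 genes, both with positive fold changes in KO muscle. As many genes passed in 36 of 100 splits of the arrays, so chance could not be excluded for this count. The effect on Rab6b in brain minus that in muscle was -2.89 ± 0.21 on the log2 scale (adjusted p = 0.000112), with an effect of 2.60 ± 0.22 in muscle and -0.29 ± 0.12 in brain, where its mean intensity was 29088 in KO and 35243 in WT. For Ppp1r14d the difference was -5.23 ± 0.64 (adjusted p = 0.0269), with an effect of 4.94 ± 0.52 in muscle and -0.29 ± 0.35 in brain. The mean intensities of Ppp1r14d in brain, 3.53 in KO and 4.82 in WT, lay near the lowest values of the arrays like that of WT muscle, so they give no direction in brain and the size of the difference is not exact. Unadjusted p was under 0.05 for 676 genes. Rab6b passed in all 28 alternatives (adjusted p = 3.37e-06 to 0.00947) and Ppp1r14d in 12 of 26 (adjusted p = 0.00365 to 0.998). Ppp1r14d was lost without any 1 of the 3 muscle WT arrays (adjusted p = 0.0503, 0.104 and 0.0695) or muscle KO array 3 (0.0689). It was also lost without brain WT arrays 1 or 3 (0.0565 and 0.0691) or any 1 of the 4 brain KO arrays (0.0881 to 0.103). The count was 8 without muscle KO array 2, and 1, Rab6b, without brain WT array 1, brain WT array 3 or any 1 of the 4 brain KO arrays. No list differed between the tissues after adjustment; the smallest p was that of neutrophil genes (permutation p = 0.0457, adjusted p = 0.823), and that of interferon response genes was 0.924 (adjusted p = 0.998).

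Across genes, log2 fold changes in brain and muscle correlated weakly, at Pearson's r of 0.147 and Spearman's rho of 0.161 over 21893 genes. Genes are not independent replicates, so the value was compared with other splits of the arrays: 14 of 100 splits gave an absolute r as large. Without muscle WT array 3, r was 0.0239. Over the 9298 genes above the median level in both tissues r was 0.378, which 1 of 100 splits, the real one, reached, with 0.371 the highest of the others. These splits regrouped each tissue on its own, although same-numbered arrays may share an animal. The number of genes past the threshold in both tissues was 0 in limma, and 1 when all 14 arrays shared 1 model. At unadjusted p under 0.01 in both tissues and in the same direction there were 2 genes, against 0.355 expected by chance, namely Celf1 and Mid1, a ubiquitin ligase gene of the X chromosome. Celf1 is the trapped gene, so its fall in both tissues follows from the design. Mid1 alone does not show more shared genes than chance gives. Mid1, chosen after its values were seen, stood at 2.61 ± 0.65 in muscle and 1.56 ± 0.40 in brain.

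Along chromosomes, the windows with the most genes that differed in KO brain lay on chromosome 2, which carries Celf1; this comparison was chosen after seeing the data. Of 228 windows of up to 100 genes, the highest counts of genes at unadjusted p under 0.01 were 11 and 8, in 2 adjacent windows that lie 134 to 333 genes distal to Celf1, and the next highest was 7. In shuffled gene orders, 1 of 1000 had a window of at least 11. In muscle, the highest count, 4, lay in the first of these windows, and 33 of 1000 shuffled orders reached it. The second window held 0 such genes in muscle. The muscle genes were not those counted in brain, of which none was at unadjusted p under 0.01 in muscle in limma (lowest 0.0165, Chst14). Of the 19 genes in brain, 10 were higher and 9 lower in KO, and 18 (94.7%) had the same sign in muscle, against 65.7% of the 329 genes at unadjusted p under 0.01 outside these windows. Neighbouring genes are not independent replicates, and same-numbered arrays of both tissues may share an animal, so these percentages carry no test. Of the 19, chosen after their values were seen, the kinase gene Pak6 stood at -1.42 ± 0.17 in brain and -1.21 ± 0.51 in muscle, and the sulfotransferase gene Chst14 at 1.16 ± 0.19 and 1.03 ± 0.33; Serinc4 lies there too. The window with Celf1 itself held 2 such genes in brain and 1 in muscle. Among the 35 splits of the brain arrays, 6, the real one included, gave a window of at least 11 genes. Over the whole of chromosome 2, 44 of 1827 genes (2.41%) were at unadjusted p under 0.01 in brain, against 305 of 19957 (1.53%) elsewhere. The 44 include Celf1 and the 19 genes of the 2 windows, so this share does not show an excess beyond those windows. As many as 44 were found in 3 of the 35 splits, the real one included, with 62 the highest of the others.

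**Figure D4:**
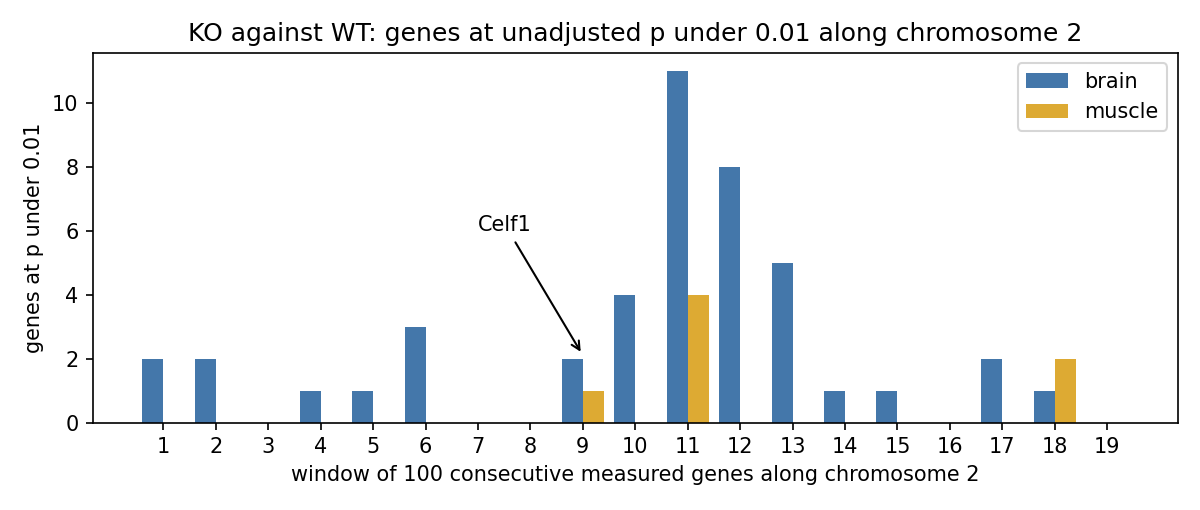
Number of genes at unadjusted p under 0.01 (KO against WT) in each window of 100 consecutive measured genes along chromosome 2, in brain and in muscle. The brain counts of 11 and 8 lie 134 to 333 genes distal to Celf1, and the window with Celf1 holds 2 in brain and 1 in muscle.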

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

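The tests of interferon, chromosome 2 and hypoxia genes were chosen only after the result was seen, except the test on other probes of the falling chromosome 2 genes and the splits of the arrays for genes, lists and the interferon list.

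On brain WT array 2 the log2 level of Nova1, a splicing regulator of neurons, was -1.50, above the other 3 WT arrays, and that of its relative Nova2 was 0.92, below the other 3, each far from the rest by Dixon's test at the 95% level. These were 2 of 112 groups tested, where chance gives 5.6. The KO effect differed between tissues for Rab6b, by -2.89 in brain minus muscle on the log2 scale, and for Ppp1r14d, by -5.23, where low intensities in brain and in WT muscle leave the size inexact. As many as 2 genes in this difference were found in 36 of 100 splits of the arrays, so chance could not be excluded. The highest count of another split was 63, and the reason for it was not tested.

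For the brain count of 5 genes, 1 of 35 splits, the real one, gave as many, and the highest of the others gave 2. This is the smallest share that 35 splits allow. The 5 include the trapped gene Celf1, and the count was 1 without WT array 3, WT array 4 or KO array 2. The splits therefore bear on the count as a whole and do not exclude chance for any single gene beside Celf1. For the 8 brain lists chance could not be excluded, as 16 of 35 splits gave as many and the highest gave 16. In muscle, 5 of 10 splits gave as many lists (real 13, highest other 17), and 10 splits are too few for a share under 0.05. For genes, a real count of 0 is reached by any split, so that 10 of 10 did (highest other 1) tests nothing.

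Interferon response genes were lower in each KO brain array than in each WT brain array. Their p at an estimated correlation was smallest in the real split (1 of 35 splits, real 0.000216, next smallest 0.0864). This is the smallest share that 35 splits allow, and the list stood out among 31 brain lists in that same split. Adjusted over the brain lists, its exact permutation p was 0.443, so the splits alone do not exclude chance for a list picked from 31. Fewer macrophages or microglia were argued against as the whole source, since interferon scores fell further than macrophage scores, by -0.56 in KO minus WT (exact permutation p = 0.0286), with 0 shared members. Neutrophil scores separated the genotypes as well and fell about as far (difference -0.029, exact permutation p = 0.971), so that comparison leaves fewer neutrophils open. With the neutrophil score as covariate, the KO effect on the interferon score was -0.79 ± 0.049 (SE), and the slope on the neutrophil score was 0.057 ± 0.047. Because neutrophil scores of KO and WT arrays did not overlap, this slope rests on the spread within each genotype. It argues against neutrophils as the whole source only if a straight line holds across both genotypes. The WT arrays high in hypoxia genes and the sex of the animals were argued against too, since the median stayed at -0.89 without those 2 arrays and at -0.87 with the Xist level as covariate. A litter or an exposure shared by the animals of 1 genotype stays open, because the labels give none and the muscle scores overlapped (exact permutation p = 0.30), which would also be seen if brain alone reacted; loss of CUGBP1 stays open beside it, so a lower interferon tone in KO brain may follow genotype or rearing.

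The 2 windows with the most genes at unadjusted p under 0.01 in brain, 19 together, lay distal to Celf1; other splits of the brain arrays had at most 14 there, which decides nothing, since the windows were picked in the real split. A candidate explanation is flanking sequence of the ES cell strain carried with the trapped allele, but it stays open, since 3 of 35 splits of the brain arrays had as many genes on chromosome 2 (real 44, highest other 62). Sequence differences under the probes alone stay open as well for the 10 genes that were higher in KO, since KO and WT mice carry the same strain label and a mismatch in WT mice would have that effect. For the falling genes they stay open although 66.7% of their other probes also lay below -0.25, past the bound set beforehand, because these were 2 of 3 probes from 2 genes, too few for that bound to decide. Loss of CUGBP1 without linked sequence also stays open: 1 of 1000 shuffled gene orders had a window as high in brain and 33 of 1000 in muscle, but 6 of 35 splits of the brain arrays did, up to 18 genes, so shuffled orders were too lenient a comparison.

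Hypoxia and glycolysis genes were lower in KO arrays of both tissues and 3 WT arrays scored high. Without brain WT arrays 3 and 4 the hypoxia median was -0.027 instead of -0.72, and 2 of the 2 remaining WT arrays lay within or below the KO range. Without muscle WT array 3 it was -0.020 instead of -0.70, with 1 of the 2 remaining WT arrays within or below that range. The glycolysis median was -0.047 instead of -0.45 without the 2 brain arrays. In muscle it was -0.28 instead of -0.42 without WT array 3, and that list still passed camera at the preset correlation (adjusted p = 0.000614). The 3 WT arrays were picked for the hypoxia genes, so the hypoxia values go with a few WT samples that stand apart but cannot show why. Handling of those samples and a KO effect stay open, and no biological explanation was tested.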

How the results depend on the processing

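Alternatives without scaling, with 50 added to each intensity, with the Xist level as covariate, with the filter on level together with trend and robust options, and without the WT arrays high in hypoxia genes were tests chosen only after the data were seen. With 22.2% to 30.4% of the probes of an array within 2-fold of its lowest value, signal over background limits what fold changes of low genes can show.

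The muscle count of 0 genes was 1 with only genes above the median level, 9 with all 14 arrays in 1 model, 1 with 50 added, and 0 to 1 with each array left out. Celf1 in muscle, at -2.77, passed with all 14 arrays in 1 model (adjusted p = 5.35e-05), where the brain arrays helped to set the spread. The SD of Celf1 was 0.078 in KO and 0.028 in WT brain, against 0.45 and 0.18 in muscle. The shared spread may therefore be too small for muscle.

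The brain count of 5 was 3 with only genes above the median level, 9 for every probe on its own, 2158 with array weights, 2 in the plain test, 14 at adjusted p under 0.10 and 0 with the array number as a block (1656 at unadjusted p under 0.05 in limma). It was 2 with all 14 arrays, 3 without scaling, 3 with the Xist level, 0 without both brain WT arrays high in hypoxia genes (784 at unadjusted p under 0.05), and 1 to 9 with each array left out. Celf1 in brain was -1.71 with the block (adjusted p = 0.230) and -1.71 without both WT arrays (adjusted p = 0.0800), where fewer samples or degrees of freedom were left; with each array left out it was -1.74 to -1.68.

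The difference between tissues, 2 genes, was 1 with array weights, 4 at adjusted p under 0.10, 1 with the block, 1 with 50 added, 1 without the 3 WT arrays high in hypoxia genes, and 1 to 8 with each array left out. With same-numbered arrays as a random block, Rab6b was -2.88 and Ppp1r14d -5.17. Genes past the threshold in both tissues numbered 1 with all 14 arrays and 0 to 0 with each array left out. The correlation between tissues, 0.147, was 0.378 over genes above the median level, 0.273 with 50 added, and 0.0239 to 0.202 with each array left out.

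The 13 muscle lists were 0 with an estimated correlation, 0 with fry, and 10 to 15 with each array left out. The 8 brain lists were 1 with an estimated correlation, 1 with fry, 0 with an estimated correlation without both WT arrays high in hypoxia genes, and 7 to 14 with each array left out.

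Directions reversed for Madd in muscle (0.26 with the mean of probes), Spink5 (-0.012) and Caps2 (-0.030) in muscle with 50 added, and Ier3 in brain (0.076 without both WT arrays). With each array left out, Trim63 in muscle ranged from -2.20 to 0.033, reversing without WT array 3. Medians of muscle lists that reversed ranged from -0.90 to 0.063 for atrophy genes and -0.54 to 0.097 for glucocorticoid genes (both without WT array 3), -0.57 to 0.24 for adipocyte genes (without WT array 1) and -0.22 to 0.83 for neutrophil genes (without WT array 2). Blood cell genes (-1.06 to -0.014, without WT array 3) and endothelial genes (-0.31 to -0.029, without KO array 3) reversed by camera direction alone. Where no smaller number of genes or samples is named, the cause was not tested. Single arrays left out aside, 604 other values of named genes in brain, 949 in muscle and 22 in the difference kept direction and side of the threshold; 35, 8 and 0 passed it newly, and 21, 0 and 4 no longer passed. With each array left out, 354, 430 and 18 kept both, 0, 1 and 0 passed newly, and 22, 0 and 10 no longer passed.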

Other observations

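Only the mean correlation of same-numbered arrays and the window on chromosome 4 were tests written beforehand; the splits for the correlation between tissues and the choice of genes named here came only after the result was seen.

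Further genes among the 19 in the 2 windows of chromosome 2 did not pass over all genes. Sqor, an enzyme of sulfide oxidation in mitochondria, stood at -1.40 ± 0.23 in brain and -0.69 ± 0.72 in muscle. The noncoding RNA gene Oip5os1 stood at -0.88 ± 0.14 in brain and -0.84 ± 0.27 in muscle, and Dnajc17, a cochaperone gene, at 0.69 ± 0.11 and 0.23 ± 0.23. Fam227b was the 1 gene of the 19 with opposite signs, at 2.02 ± 0.42 in brain and -1.23 ± 0.46 in muscle. Gchfr and Ppp1r14d, with high values in KO muscle, lie in the first of these windows too, at -0.14 ± 0.20 and -0.29 ± 0.35 in brain, where Ppp1r14d was too low to give a direction.

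Among the genes in the list of RNA-binding proteins related to CUGBP1 and MBNL, none of which passed over all genes, Mbnl3 stood at 0.73 ± 0.27, Nova1 at 0.39 ± 0.15 and Nova2 at -0.44 ± 0.17 in KO brain. In KO muscle, Celf5 stood at 0.48 ± 0.30, Ptbp1 at 0.32 ± 0.27 and Elavl3 at -0.47 ± 0.31. The 25055 probes without a gene name gave 0 calls in limma in either tissue, with 618 in muscle and 1397 in brain at unadjusted p under 0.05.

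Same-numbered brain and muscle arrays may come from the same animals, which the labels do not state. Deviations from the group means over 9282 genes correlated between same-numbered arrays at a mean r of 0.226, and 2 of 36 numberings gave a mean as high (exact one-sided permutation p = 0.0556, highest other 0.2498). The single values were 0.165, 0.421 and 0.428 for WT and 0.294, 0.0930 and -0.0458 for KO. The bound set beforehand would have counted p of at least 0.05 against this, which was too loose, since a p just past a threshold does not show absence and only 36 numberings exist. The side of Xist, low or high, was the same in 6 of 6 pairs. Among these pairs the low arrays were WT array 1 and KO array 1 in both tissues. Other numberings that keep these arrays together also give 6 of 6, so this count does not settle it.

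In another split of the brain arrays, 18 genes in a window on chromosome 4 differed between the sides, 9 higher and 9 lower on the side of WT arrays 1, 3 and 4 and KO array 4. Among them Zfp981 differed by 2.28, Masp2 by 2.35, Zfp982 by -2.34 and Disp3 by -1.46. With the signs of the lower genes turned, their mean scores were 0.91 and 1.00 on brain WT arrays 3 and 4 and 0.67 on KO array 4, 0.13 on WT array 1, and -0.89 to -0.13 on the other 4. These genes were picked for the split, so only the muscle arrays test it: there, with the same signs, arrays numbered like the higher side scored above the others by 0.83 (exact one-sided permutation p = 0.0667, the smallest that 15 groupings allow). Both of those arrays were WT, so a KO effect on these genes is not set apart. The value is consistent with same-numbered samples of both tissues from 1 animal, or with relatives that share a segregating segment, and 6 arrays cannot settle it.

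The correlation of fold changes between tissues, 0.147, was reached in absolute size by 14 of 100 splits, with 0.210 the highest of the others, so chance could not be excluded. Among the 20 joint regroupings of the array numbers, 7 reached 0.147. Over the 9298 genes above the median level in both tissues, r of 0.378 was reached by the real split alone, with 0.371 the highest of the others. For these genes the joint regroupings were not run and no array was left out. This small margin therefore does not settle whether chance is excluded for them.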
